A study of Homo sapiens with 6 samples.

How the data were processed

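RNA was measured by sequencing in SKOV3ip1 cells, a human ovarian adenocarcinoma line derived from SKOV3 and grown in culture. Per the labels' protocols, cells were transfected with 2 µg of either BARD1 siRNA or control siRNA using a cationic lipid reagent and kept for 48 h. Total RNA was column-purified and libraries were made after poly(A) capture. The labels name the material both as cells and as tumors. The protocols describe cultured cells, and the libraries are treated as such here. The sample titles number 3 biological replicates per group, which gives 6 libraries. Whether replicates were transfected on separate days is not given in the sources used here, and p-values measure the spread between these cultures. The siRNA sequences are not given in the sources used here, nor is whether the numbers after the siRNA name stand for different siRNAs.

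The deposited table holds raw read counts per gene, whole numbers with no normalization by the authors. Per the submitters' processing notes, HISAT2 and CASAVA were used with the GRCh38 (hg38) genome; their versions, the counting program, the annotation release and the strand setting are not given in the sources used here. The deposited table also gives each gene's length, which served no test here. All 58735 gene identifiers of the table are found in GENCODE release 29, with the same start and end for 58724 and the same name for 58708. Every count column matched the labels of a sample. Because the strand setting is not stated, reads of overlapping genes cannot be assigned with certainty. Of the 108 genes chosen by the naming rule, 26 overlap another tested gene, and for 9 of these the partner had the higher mean count, among them MCAM, ESRP2, FOSB, RSAD2, DDIT3, CCNE2, PRIM1 and MT-ATP6. Reads may likewise have been divided among near-identical copies, so values of CXCL1, CXCL2 and CXCL3, of CD24, of the histone genes, of HSPA1A and HSPA1B, of the AKR1C genes and of ribosomal protein genes with many pseudogenes are uncertain.

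Totals ranged from 16621108 to 17743404 counts per library, so that 1 CPM stood for about 17 reads. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, using the robust quasi-likelihood test (glmQLFit and glmQLFTest) on the counts, TMM scaling factors and a design with the group alone. The filterByExpr function with its minimum count of 10 and minimum total of 15 left 15271 genes of the 29419 with any count. Benjamini-Hochberg adjustment ran over all tested genes and the threshold was an adjusted p of 0.05. Fold changes are BARD1 siRNA over control siRNA. Their standard error (SE) is the absolute log2 fold change divided by the square root of the F statistic. Normalised CPM values are given as mean ± SD over the 3 libraries of a group. Where the 3 libraries of a group held 0 counts of a gene, the fold was computed against a floor of 3 counts over the group, which covers counting error only.

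The 26 gene lists were written before the data were examined, from textbook knowledge, and were tested with camera (limma 3.58.1), two-sided, with a preset inter-gene correlation of 0.01 and adjustment over the lists. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Members called are counted over all tested genes and adjusted over the list alone. Several genes stand in more than 1 list. The genes named were set by a rule fixed before the data were examined. It takes BARD1, the 10 protein-coding genes with the largest and the 10 with the smallest log2 fold change among those past the threshold, with a mean log2 CPM of at least 2 and no overlap between the groups. It adds up to 4 members of each list with the largest absolute change past the threshold, and VEGFA, KDR, FLT1, FGF2, ANGPT2, CXCL8, BRCA1 and THBS1 in any case. Members named because few of a list went against it or missed the threshold, and further examples of a list, were chosen after their values were seen. Results for 1 of the lists and for some genes that the rule names are not reported here.

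Alternatives were RLE, upper-quartile and no composition scaling, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 1 CPM in 3 libraries, protein-coding genes only, a replicate block, the test without robust estimation, and leaving out each library in turn. An alternative added after the data were seen tested each list without members held by other lists, and each list added later without members of the 26. On counts simulated from these libraries' means with 14994 genes, 48 to 50 genes were changed at each size. The edgeR test of BARD1 siRNA against control siRNA recovered 25% of genes changed by 0.3 on the log2 scale. It recovered 56% at 0.5, 82% at 1 and 93.9% at 2, and 5.22% of its calls were false. In the real data 42.3% of tested genes were called, and the adjusted threshold is less strict when more genes change. These rates hold for the simulated setting and are not those of the real comparison. Counts of replicate pairs differed by more than sampling noise, with chi-square over degrees of freedom from 3.29 to 7.71, so each library was kept as its own replicate.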

Results

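The series compared SKOV3ip1 ovarian adenocarcinoma cells 48 h after transfection with BARD1 siRNA against the same cells given control siRNA, with 3 libraries in each group. BARD1 is the RING-domain partner of BRCA1, with which it forms a ubiquitin ligase that acts in homologous recombination. The design asks how silencing of BARD1 affects pathways of tumour angiogenesis. Control siRNA libraries held 17304736, 16621108 and 17704645 gene counts, and BARD1 siRNA libraries held 16661374, 17267254 and 17743404. Between 21867 and 22821 genes had at least 1 count per library. The first principal component of the log CPM values took 61.9% of the variance and separated the groups. The biological coefficient of variation among replicates was 7.20%. TMM factors were 1.02 to 1.03 in control siRNA and 0.977 to 0.982 in BARD1 siRNA libraries. Mitochondrially encoded genes took 5.23% to 5.73% of counts in control siRNA and 4.93% to 5.15% in BARD1 siRNA libraries.

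BARD1 itself (ENSG00000138376, GRCh38 chromosome 2, 214725646 to 214809711, minus strand) was lower in every BARD1 siRNA library than in any control siRNA library. Its counts were 805, 644 and 887 with control siRNA and 96, 110 and 169 with BARD1 siRNA. Normalised expression fell from 44.3 ± 5.85 to 7.38 ± 2.04 CPM (SD, n = 3 per group), a 5.98-fold reduction (log2 fold change −2.58, SE 0.14, edgeR quasi-likelihood adjusted p = 1.21e-15). BRCA1 mRNA was 1.58-fold lower, at 151 ± 12.2 CPM in control siRNA and 95.5 ± 5.19 CPM in BARD1 siRNA cells (edgeR adjusted p = 3.22e-13).

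The comparison of the 2 groups showed a broad change. Of the lists fixed beforehand, NF-κB targets, immediate early genes and genes of ATF4 and the unfolded protein response had the highest medians and passed the list test. Genes of G2/M and mitosis had the lowest median and also passed. Of 15271 genes tested, 3355 were higher and 3107 lower with BARD1 siRNA in the edgeR test. A change of at least 2-fold was reached by 684 of the higher and 297 of the lower genes. All 3 libraries of 1 group lay above all 3 of the other for 6137 of the called genes, and for 50.4% of all tested genes against 10% by chance. The direction of small changes depended on the scaling. With upper-quartile factors 2815 genes were higher and 3975 lower, and the share of higher genes among the called went from 51.9% to 41.5%. With library size alone that share was 42.2%.

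The naming rule ranked called protein-coding genes with a mean log2 CPM of at least 2 and no overlap between the groups. Among these, the 10 with the largest increases were CSF2, IL1B, IL1A, ATF3, CXCL8, CCL20, GDF15, FOSB, CXCL2 and SOCS1. CSF2, which encodes the cytokine GM-CSF, rose from 0.134 ± 0.0682 to 19.8 ± 1.12 CPM (log2 fold change 7.14, SE 0.28, edgeR adjusted p = 4.06e-28). CXCL8, which encodes the neutrophil chemoattractant interleukin-8, was the most abundant of the 10 and rose from 35.3 ± 1.42 to 1395 ± 64.3 CPM (log2 fold change 5.30, SE 0.06, edgeR adjusted p = 8.85e-53). The interleukin-1 genes IL1A and IL1B rose by 5.70 and 6.13 on the log2 scale. GDF15, a stress-induced cytokine of the TGF-beta superfamily, rose from 2.37 ± 0.155 to 76.4 ± 0.726 CPM, a 32.1-fold increase. The remaining increases were 5.35 for ATF3, 5.30 for CCL20, 4.87 for FOSB, 4.80 for CXCL2 and 4.74 for SOCS1, as log2 fold changes.

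By the same rule, the 10 with the largest decreases were EPHA4, KIT, BARD1, PCDH10, CAVIN2, VAV3, MXRA5, ZFHX4, CDKN2C and TRIM6. EPHA4, an ephrin receptor, fell from 10.0 ± 0.922 to 0.870 ± 0.50 CPM (log2 fold change −3.52, SE 0.27, edgeR adjusted p = 1.89e-15). KIT, the stem cell factor receptor, fell from 7.51 ± 1.28 to 0.754 ± 0.20 CPM, a 9.90-fold reduction. CDKN2C, which encodes the CDK4 and CDK6 inhibitor p18, fell from 49.1 ± 2.94 to 11.5 ± 1.49 CPM. The others had log2 fold changes of −2.54 for PCDH10, −2.50 for CAVIN2, −2.21 for VAV3, −2.13 for MXRA5, −2.11 for ZFHX4 and −2.06 for TRIM6.

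**Figure D1:**
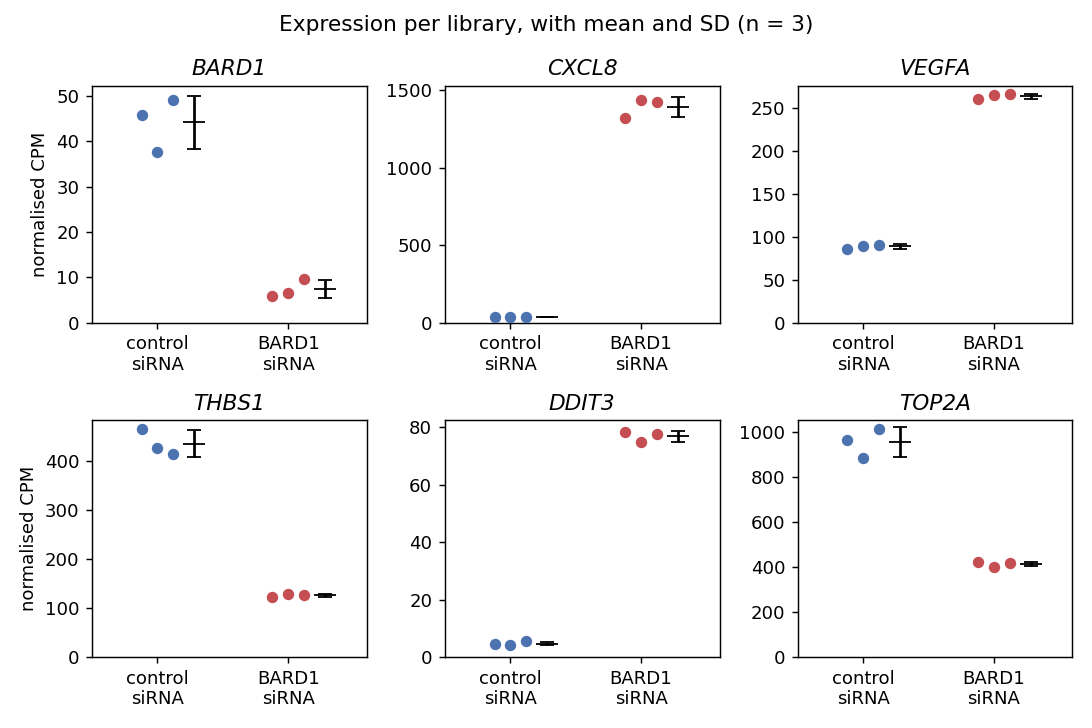
Normalised CPM (vertical axes, from 0) of BARD1, CXCL8, VEGFA, THBS1, DDIT3 and TOP2A in each library; points are libraries and the bar beside each group is its mean with SD (n = 3). BARD1 went from a mean of 44.3 CPM with control siRNA to 7.38 CPM with BARD1 siRNA, and the groups do not overlap for any of the 6 genes.

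Pro-angiogenic factors, the group closest to the question of the design, rose as a list. Of 51 tested members 35 rose and 9 fell, with a median log2 fold change of 0.80 (camera adjusted p = 3.30e-41; 0.00216 with an estimated correlation). When adjusted over the list alone, 36 rose and 9 fell. VEGFA, the main growth factor of endothelial cells, rose 2.97-fold from 88.9 ± 2.46 to 264 ± 3.06 CPM (log2 fold change 1.57, SE 0.05, edgeR adjusted p = 1.97e-30). FGF2, a mitogen of endothelial cells, rose 1.47-fold from 249 ± 7.79 to 365 ± 14.6 CPM (edgeR adjusted p = 1.19e-13). The strongest members, CSF2, IL1B, IL1A and CXCL8, also stood in the NF-κB list. The 9 members shared with that list all rose, with a median of 4.80. The other 42 had a median of 0.63, with 26 higher and 9 lower, in a split of the list made after the data were seen. Among the members that fell were BMP4 at −2.05, FGF18 at −1.72, HGF at −1.39, MDK at −1.07 and APLN at −0.98. ANGPT2, a ligand of the TIE2 receptor, had 7 counts over the control siRNA and 13 over the BARD1 siRNA libraries and was too low to test.

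Anti-angiogenic factors went both ways. THBS1, which encodes the angiogenesis inhibitor thrombospondin-1, fell 3.46-fold from 436 ± 27.0 to 126 ± 3.58 CPM (log2 fold change −1.79, SE 0.05, edgeR adjusted p = 1.97e-33). SPRY4 and SPRY2, inhibitors of receptor tyrosine kinase signalling, rose by 2.57 and 1.63 on the log2 scale, and the metalloprotease ADAMTS9 rose by 1.69. Of 25 tested members 10 rose and 6 fell, or 10 and 7 when adjusted over the list alone, and the list did not pass (median 0.11, camera adjusted p = 0.0811; 0.269 with an estimated correlation). It passed without members of other lists, at an adjusted p of 0.0224 (0.152 with an estimated correlation), and with no filter on low counts, at 0.0143. Over the camera alternatives the adjusted p reached up to 0.269, and fry gave 0.000945.

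Receptors of angiogenic growth factors did not pass as a list in camera. Of 25 tested members 12 rose and 6 fell, also when adjusted over the list alone (median 0.17, camera adjusted p = 0.123; 0.274 with an estimated correlation). The fry test, which compares with no change rather than with other genes, called them higher, at an adjusted p of 0.000674. The fibronectin receptor subunit ITGA5 rose from 75.1 ± 2.53 to 209 ± 5.74 CPM, a log2 fold change of 1.48, and the netrin receptor UNC5B rose by 1.29. NOTCH3 and FGFR2 had log2 fold changes of −1.27 and −0.96. KDR, which encodes VEGF receptor 2, had 33 counts over the control siRNA and 42 over the BARD1 siRNA libraries, a difference within the replicate spread (log2 fold change 0.40, SE 0.54, edgeR adjusted p = 0.591). FLT1, which encodes VEGF receptor 1, had 0 counts in all 6 libraries, which allows up to 3 counts over a group.

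Targets of hypoxia-inducible factors rose as a list, although some enzymes of glycolysis within it fell. Of 36 tested members 17 rose and 5 fell, and 17 and 6 when adjusted over the list alone (median 0.24, camera adjusted p = 2.37e-05; 0.0253 with an estimated correlation). NDRG1 rose by 2.63, DDIT4 by 2.24, BHLHE40 by 1.99 and ADM, which encodes the vasodilator peptide adrenomedullin, by 1.70 on the log2 scale. The 5 that fell were CA9, the hypoxia-induced carbonic anhydrase, at −1.08, LDHA at −0.68, ENO1 at −0.25, PGK1 at −0.23 and EGLN1 at −0.16. Without the members of the ATF4 list, among them VEGFA and DDIT4, 14 of 33 rose and 5 fell, with a median of 0.18. The unadjusted camera p was 0.00165, and 0.0254 with an estimated correlation. Adjustment ran here only over the lists split after the data were seen, not over all fixed lists, and left both values unchanged. They are therefore not comparable with the adjusted values of the fixed lists. Without members of any other list 7 of 17 rose and 2 fell, at an adjusted p of 0.0272, and the call was lost with an estimated correlation, at 0.152. Both tests were added after the data were seen.

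Glycolysis genes had a median log2 fold change of −0.15. Of 22 tested members 11 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.0475; 0.335 with an estimated correlation). LDHA, which reduces pyruvate to lactate, fell from 3288 ± 129 to 2058 ± 58.4 CPM, and LDHB and PGAM1 fell by 0.47 and 0.44 on the log2 scale. Hexokinase 2 (HK2) rose by 0.57. The call of this list was lost with 1 CPM in 3 libraries, at an adjusted p of 0.0528, and with protein-coding genes only, at 0.0627. It was also lost with the replicate block, at 0.0550, and without any of 4 libraries. Those values were 0.0627 without control siRNA replicate 2 and 0.0546, 0.0536 and 0.0707 without BARD1 siRNA replicates 1, 2 and 3. Over all camera alternatives the adjusted p ranged from 0.00745 with limma-voom to 0.335, and fry, which compares with no change, gave 0.00290.

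Targets of NF-κB, the transcription factor family of inflammatory signalling, had the largest median of the 26 lists, at 2.21. Of 37 tested members 32 rose and 0 fell, and 34 rose when adjusted over the list alone (camera adjusted p = 2.14e-135; 0.00216 with an estimated correlation). The feedback inhibitors TNFAIP3 and NFKBIA rose by 4.65 and 2.25 on the log2 scale, the adhesion molecule ICAM1 by 4.20 and TNF by 3.63. The 5 members that did not pass over all genes were TNFAIP8, PTGS2, LTB, SAA1 and CFB, with log2 fold changes from 0.11 to 1.31. Immediate early genes rose in the same way, with 19 of 21 higher and 0 lower, or 20 higher when adjusted over the list alone (median 1.65, camera adjusted p = 1.80e-52; 0.00481 with an estimated correlation). The phosphatase genes DUSP5 and DUSP1, whose products inactivate MAP kinases, rose from 19.7 ± 1.00 to 228 ± 5.70 CPM and from 25.9 ± 1.85 to 258 ± 8.2 CPM. EGR1 and KLF2 did not pass, with log2 fold changes of 0.07 and 0.42.

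Genes of the ATF4 pathway and the unfolded protein response, which answer amino acid shortage and misfolded protein in the endoplasmic reticulum, rose in 36 of 41 cases and fell in 1. The same counts held when adjusted over the list alone (median 1.39, camera adjusted p = 1.49e-81; 0.00421 with an estimated correlation). DDIT3, which encodes the transcription factor CHOP, rose 16.2-fold from 4.72 ± 0.624 to 76.9 ± 1.86 CPM (log2 fold change 4.02, SE 0.11, edgeR adjusted p = 1.33e-35). PPP1R15A, the stress-induced regulatory subunit of the eIF2α phosphatase, rose by 3.81 and the glutathione-degrading enzyme CHAC1 by 3.75 on the log2 scale. The endoplasmic reticulum chaperone HSPA5 rose by 3.10 and HERPUD1 by 3.45. SLC7A5, an amino acid transporter, was the 1 member that fell, at −0.24.

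Apoptosis regulators of both kinds were among the members that rose. Of 38 tested members 19 rose and 4 fell, or 20 and 6 when adjusted over the list alone (median 0.35, camera adjusted p = 1.09e-05; 0.0518 with an estimated correlation). BCL2A1, an anti-apoptotic NF-κB target, had 0 counts with control siRNA and 89 with BARD1 siRNA, at least 29.6-fold higher, a bound that leaves the list median at 0.35. BBC3, a pro-apoptotic BH3-only gene, rose from 1.98 ± 0.345 to 24.6 ± 0.955 CPM. The pro-apoptotic HRK rose by 4.70 and the death receptor gene TNFRSF10B rose from 82.6 ± 6.61 to 406 ± 7.12 CPM. The 4 that fell were CASP6 at −0.83, BIRC5 at −0.67, CASP2 at −0.38 and BOK at −0.26.

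Interferon-stimulated genes rose in 24 of 40 cases and fell in 2, or 26 and 4 when adjusted over the list alone. Their median was 0.56 (camera adjusted p = 0.00550; 0.0598 with an estimated correlation). RSAD2 and OASL rose by 4.34 and 3.35 on the log2 scale but stayed at 1.68 ± 0.291 and 1.62 ± 0.483 CPM with BARD1 siRNA. GBP1 rose by 2.17, and the transcription factor IRF1 rose from 18 ± 1.6 to 65.9 ± 4.04 CPM. Among those that fell was HERC5 at −0.39. IFIT1 at −0.45 and MX1 at 0.49 did not pass. The interferon gene IFNB1 had 0 counts in all 6 libraries.

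Genes of the cell cycle fell together. Of 50 G2/M and mitosis genes 48 fell and 0 rose, also when adjusted over the list alone (median −0.74, camera adjusted p = 4.61e-35; 0.0190 with an estimated correlation). The mitotic kinesins KIF20A and KIF4A fell 2.83-fold and 2.41-fold, the centrosomal kinase NEK2 fell 2.48-fold and TOP2A, which encodes topoisomerase IIα, fell from 956 ± 65.4 to 413 ± 9.91 CPM. PRC1 and CKS1B, at −0.30 and −0.08, did not pass. Of 49 DNA replication and G1/S genes 45 fell and 1 rose, also when adjusted over the list alone (median −0.53, camera adjusted p = 9.15e-17; 0.0598 with an estimated correlation). CCNE2, which encodes cyclin E2, fell 2.31-fold, and TYMS, E2F2 and PRIM1 fell by 1.06, 1.00 and 0.99 on the log2 scale. CCNE1, which encodes cyclin E1, rose by 0.43. Outside these lists, the inhibitor of cyclin-dependent kinases CDKN1A rose from 12.8 ± 1.01 to 121 ± 4.03 CPM, and the growth arrest gene GADD45A rose by 2.69 on the log2 scale.

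Genes of homologous recombination and the BRCA1 complexes had 24 lower and 2 higher of 38 tested members, or 25 and 2 when adjusted over the list alone. Their median was −0.31 (camera adjusted p = 0.000146; 0.262 with an estimated correlation). FANCM, the DNA translocase of the Fanconi anaemia pathway, fell by 0.72 on the log2 scale, H2AFX by 0.71, BRCC3 by 0.70 and RAD51C by 0.67. The 2 that rose were UIMC1 at 0.35 and RNF168 at 0.41. BARD1 was not a member of this list. Factors of cleavage stimulation and polyadenylation, the complex that BARD1 binds through CSTF1, had 7 lower and 0 higher of 21 tested, also when adjusted over the list alone (median −0.05, camera adjusted p = 0.197; 0.335 with an estimated correlation). CSTF1 fell by 0.40, CPSF2 by 0.40, CSTF2 by 0.37 and CPSF3 by 0.28.

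**Figure D2:**
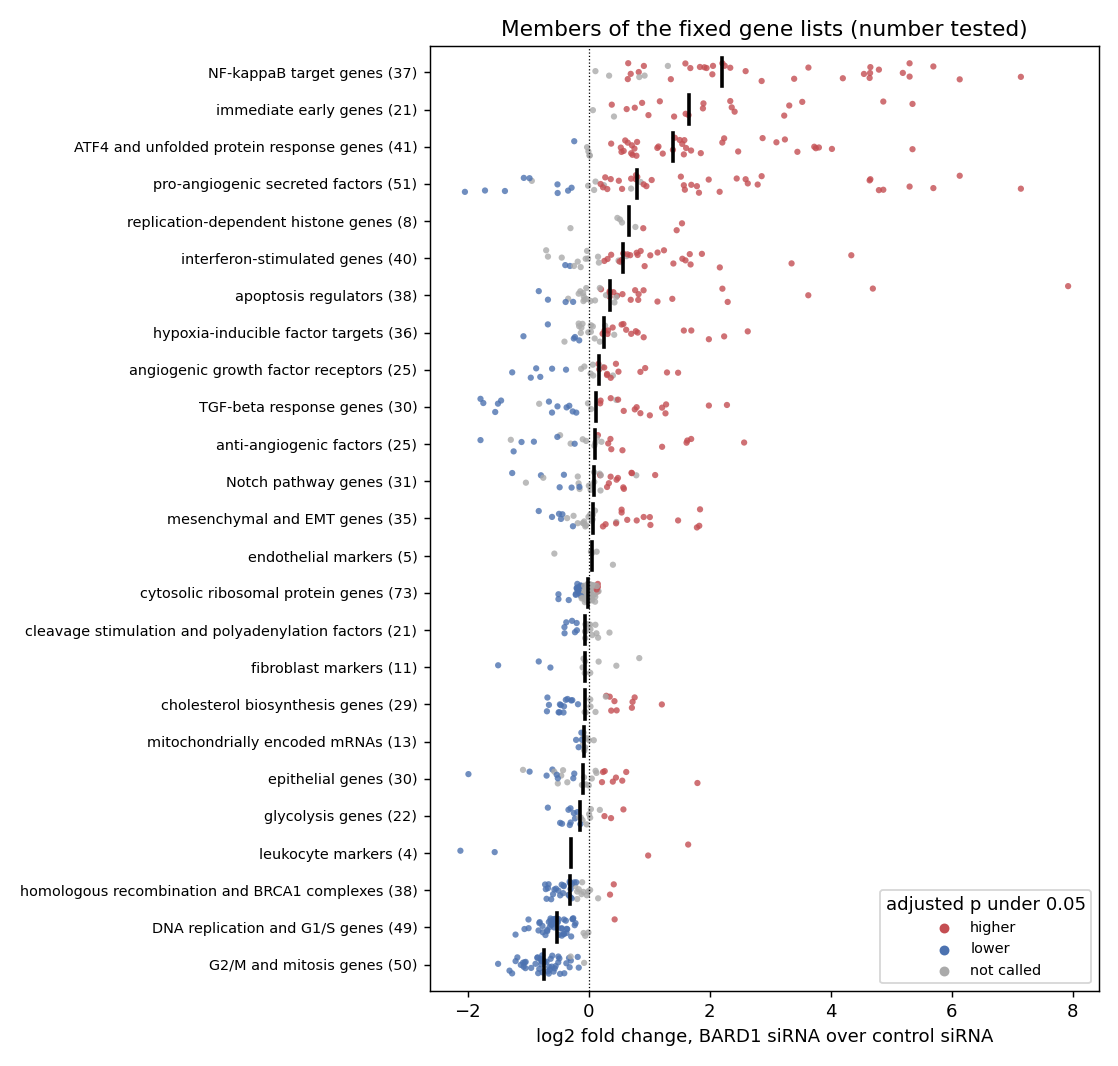
Log2 fold change of BARD1 siRNA over control siRNA (horizontal axis) of the tested members of each reported gene list (rows, with the number tested); points are genes, red higher, blue lower and grey not called at an adjusted p of 0.05, and black bars are medians; the point at 7.93 is the fitted value of BCL2A1, which had 0 counts with control siRNA. The NF-κB list has the highest median, at 2.21, and the G2/M and mitosis list the lowest, at −0.74.

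TGF-β response genes split into groups of opposite direction. Of 30 tested members 14 rose and 12 fell, or 15 and 13 when adjusted over the list alone (median 0.11, camera adjusted p = 0.939; 0.958 with an estimated correlation). ID1, an inhibitor of differentiation induced by BMP signalling, fell from 920 ± 67.8 to 275 ± 12.3 CPM, while the BMP antagonist NOG rose by 2.28 on the log2 scale to 1.98 ± 0.180 CPM. The direction of this list turned with upper-quartile factors and with library size alone. Without members of other lists, an alternative added after the data were seen, it was lower (median −0.21, camera adjusted p = 0.0280; 0.244 with an estimated correlation), and over all alternatives the adjusted p ranged from 0.0280 to 0.995. Notch pathway genes had 11 higher and 6 lower of 31, also when adjusted over the list alone (median 0.09, camera adjusted p = 0.397; 0.464 with an estimated correlation). HEY1, a transcriptional target of Notch, rose by 1.10 and ADAM17 by 0.71 on the log2 scale, while HES2 had a change of −0.79.

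Epithelial genes had 8 higher and 8 lower of 30, or 8 and 9 when adjusted over the list alone (median −0.10, camera adjusted p = 0.0366; 0.122 with an estimated correlation). CD24 fell 3.97-fold from 1029 ± 54.8 to 259 ± 11.2 CPM, though it has near-identical copies elsewhere in the genome. KRT7 and ESRP2 fell by 0.98 and 0.70 on the log2 scale and CLDN4 rose by 1.80. The call of the list was lost with limma-voom, at an adjusted p of 0.129, and without BARD1 siRNA replicate 3, at 0.0707, in a range of 0.0134 to 0.129 over the camera alternatives. The fry test gave 0.00132. Mesenchymal genes had 14 higher and 6 lower of 35, or 15 and 6 when adjusted over the list alone (median 0.06, camera adjusted p = 0.0403; 0.122 with an estimated correlation). The matrix glycoprotein TNC rose from 16.4 ± 0.185 to 58.2 ± 1.83 CPM, and MMP14 rose by 1.79 and ZEB2 by 1.84 on the log2 scale. ZEB2 had 0.470 ± 0.456 CPM with control siRNA and lost its call with DESeq2, at an adjusted p of 0.232. Its call was also lost without control siRNA replicate 2 and without BARD1 siRNA replicates 2 and 3, at edgeR adjusted p of 0.0606, 0.0985 and 0.0546. This list's call was lost under both scalings named above, without control siRNA replicate 2 and without BARD1 siRNA replicates 2 and 3, at adjusted p from 0.0536 to 0.0629. It was also lost with limma-voom, with 1 CPM in 3 libraries and with protein-coding genes only, at 0.0987, 0.0596 and 0.0627. Without members of other lists the adjusted p was 0.364, the highest over the camera alternatives, and the lowest of these was 0.00399 with no filter on low counts. The fry test, which compares with no change rather than with other genes, gave 7.41e-05.

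Cholesterol biosynthesis genes had 9 higher and 14 lower of 29, also when adjusted over the list alone (median −0.07, camera adjusted p = 0.568; 0.658 with an estimated correlation). INSIG1, which retains SREBP precursors in the endoplasmic reticulum, rose 2.31-fold, and CYP51A1 and STARD4 rose by 0.76 and 0.71 on the log2 scale. Ribosomal protein genes had 4 higher and 18 lower of 73, or 4 and 17 when adjusted over the list alone (median −0.02, camera adjusted p = 0.139; 0.719 with an estimated correlation). RPS26 and RPL24 had a change of −0.50 each, RPLP0 of −0.33 and RPL21 of −0.21. That list was lower with upper-quartile factors, library size alone and without control siRNA replicate 1, at adjusted p of 0.0293, 0.0344 and 0.0362, in a range of 0.0293 to 0.719. Mitochondrially encoded mRNAs had 4 lower and 0 higher of 13, also when adjusted over the list alone (median −0.08, camera adjusted p = 0.281; 0.743 with an estimated correlation). The 4 were MT-ND6 at −0.21, MT-ATP6 at −0.17, MT-ND5 at −0.12 and MT-CYB at −0.11. The calls of MT-ND5 and MT-CYB were each lost without control siRNA replicate 1, BARD1 siRNA replicate 1 or BARD1 siRNA replicate 2, at edgeR adjusted p from 0.0820 to 0.254. Replication-dependent histone genes, whose mRNAs mostly lack poly(A) tails, had 3 higher and 0 lower of 8, also when adjusted over the list alone (median 0.66, camera adjusted p = 0.435; 0.554 with an estimated correlation). HIST2H2BE rose by 1.54, HIST1H2BC by 1.45 and HIST1H1E by 0.90 on the log2 scale, all from under 2 CPM. HIST1H2BC lost the call with no filter on low counts, at an edgeR adjusted p of 0.0551. It was also lost without control siRNA replicates 2 and 3 and BARD1 siRNA replicates 1 and 2, at edgeR adjusted p from 0.0520 to 0.138. HIST1H1E lost the call without control siRNA replicate 2 and BARD1 siRNA replicates 2 and 3, at edgeR adjusted p from 0.0593 to 0.0914.

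Markers of other cell types did not pass as lists. Of 18 endothelial markers 5 could be tested and 0 passed, also when adjusted over the list alone. Their median was 0.06 while camera gave the opposite direction (adjusted p = 0.939; 0.958 with an estimated correlation). Of 24 leukocyte markers 4 could be tested, with 2 higher and 2 lower, also when adjusted over the list alone (median −0.29, camera adjusted p = 0.708; 0.818 with an estimated correlation). Among these were ITGAX at 1.64, LAPTM5 at 0.98 and CORO1A at −1.56. PTPRC, TYROBP, LYZ and CD68 had 0 counts in all 6 libraries. Of 20 fibroblast markers 11 could be tested, with 3 lower and 0 higher, also when adjusted over the list alone (median −0.07, camera adjusted p = 0.348; 0.646 with an estimated correlation). The 3 were MCAM at −1.50, COL3A1 at −0.83 and MFAP5 at −0.63.

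Camera with the preset correlation thus called 9 of the 26 lists higher and 5 lower. With an estimated correlation 6 were higher and 1 lower. Among the 6 higher lists were the pro-angiogenic, hypoxia, NF-κB, ATF4 and immediate early lists, and the 1 lower list was that of G2/M and mitosis genes. Among lists that camera did not call, fry also called the Notch and histone lists higher, at adjusted p of 0.000741 and 0.00205, and the polyadenylation factors lower, at 0.00307. For the lists above with 0 members in a direction, the edgeR test at an unadjusted p under 0.05 gave 1 endothelial marker lower and 1 fibroblast marker higher and 0 elsewhere. DESeq2 also gave 0 in each, and limma-voom 1 higher factor of polyadenylation and 0 elsewhere. Camera with the preset correlation also called 5 to 11 lists in the other 9 ways of splitting the 6 libraries into 3 and 3. Those splits mix both siRNAs on each side and keep part of the difference between them, so this is not a rate of false calls. The design holds 1 knockdown condition and no rescue, so every difference given here is between cultures that received different siRNAs.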

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

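The tests of lists without members of other lists were added only after the data were seen. The counts of genes higher and lower, of those changed at least 2-fold and the change of BARD1 stayed within 1.5 times or on the same side under each alternative run. BARD1 ranged from −2.83 to −2.45 on the log2 scale over the fits without a library. Genes higher ranged from 2815 with upper-quartile factors to 3390, and genes lower from 2651 without BARD1 siRNA replicate 2 to 3975 with upper-quartile factors. Among genes called both here and in any alternative, 0 had opposite directions, and DESeq2 called 6070 of the same genes.

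The number of lists called lower moved from 5 to 1 with an estimated correlation. It ranged from 3 to 6 over the fits without a library, the 3 without BARD1 siRNA replicate 3. The cause was not tested. The replicate block gave 3390 genes higher, 3122 lower and 4 lists lower, glycolysis coming to an adjusted p of 0.0550, and 6402 of its 6512 calls were shared with the fit without it. Libraries with the same number did not deviate together, with correlations of −0.009, −0.015 and −0.022, so no pairing by number was visible. Whether cultures with the same number were handled together is not given in the sources used here.

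The direction turned in 11 list tests, of 3 lists. The endothelial list turned with limma-voom (adjusted p = 0.943) and fry (0.797), and its adjusted p ranged from 0.749 to 0.957 without a library, turning without control siRNA replicate 2 and BARD1 siRNA replicates 1 and 3. The leukocyte list turned with 1 CPM in 3 libraries (0.995), where fewer genes are tested. The TGF-β list turned with upper-quartile factors (0.906) and library size alone (0.938), ranged from 0.749 to 0.930 without a library, turning without control siRNA replicates 1 and 3, and turned to a call without members of other lists (0.0280, and 0.244 with an estimated correlation). The cause was not tested. Of the comparisons of named genes with their alternatives, 1658 kept direction and call, 18 lost the call and 0 turned. Of those of lists, 422 stayed, 25 lost the call and 10 gained it. Depth limits genes such as KDR, with 8 to 20 counts per library.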

Other observations

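The 7 lists of this and the next paragraph, the choice of the word TATTTAT and the tests of scaling came only after results were seen. Genes of the oxidative stress response controlled by NRF2 rose in 18 of 23 cases and fell in 0 (median 0.52, camera adjusted p = 1.87e-19; 0.0236 with an estimated correlation). HMOX1, which encodes heme oxygenase 1, rose by 4.60 on the log2 scale, OSGIN1 by 2.19 and AKR1C1 by 2.75, though reads of the AKR1C genes can be shared. Feedback genes of MAP kinase signalling had 17 higher and 1 lower of 21 (median 0.83, camera adjusted p = 1.31e-25; 0.00215 with an estimated correlation), and the 1 that fell was EPHA4. Several of these genes, such as DUSP1, DUSP5, SPRY2 and SPRY4, also stand in the fixed lists. Without members of the fixed lists 9 of 11 rose and 1 fell (median 0.69, camera adjusted p = 0.000155; 0.0331 with an estimated correlation). Autophagy and lysosome genes had 14 higher and 2 lower of 25 (median 0.35, camera adjusted p = 1.48e-06; 0.0513 with an estimated correlation), led by SQSTM1 at 2.42 and WIPI1 at 2.16. Circadian clock genes had 11 higher and 3 lower of 18 (median 0.36, camera adjusted p = 0.000124; 0.0239 with an estimated correlation), with NR1D1 at 3.00, PER1 at 1.29 and DBP, in the opposite direction, at −1.80. Without members of the fixed lists the clock genes had an adjusted p of 0.0103, and 0.0669 with an estimated correlation.

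BMP-SMAD response genes had 6 higher and 6 lower of 15 (median −0.35, camera adjusted p = 0.00337; 0.217 with an estimated correlation). Without members of the fixed lists 6 genes were left, and the call was lost (adjusted p = 0.184; 0.394 with an estimated correlation). The members that fell included all 4 inhibitors of differentiation, ID1 at −1.74, ID2 at −1.45, ID3 at −1.50 and ID4 at −1.64, and the feedback inhibitor SMAD6 at −1.55. The 6 that rose were the inhibitors NOG at 2.28, BAMBI at 1.28 and SMAD7 at 0.58, and UNC5B at 1.29, MSX1 at 1.16 and HEY1 at 1.10. BMP4, a ligand of this pathway, fell by 2.05 on the log2 scale. Heat shock genes had 8 higher and 3 lower of 16 (median 0.17, camera adjusted p = 0.000124; 0.0239 with an estimated correlation), led by HSPA1A at 2.37 and HSPA1B at 2.05, which are near-identical copies. Cytosolic aminoacyl-tRNA synthetase genes had 9 higher and 5 lower of 18 (median 0.09, camera adjusted p = 0.00623; 0.222 with an estimated correlation).

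A scaling factor moves all genes of a library alike, so it cancels when a list is taken against the median of all tested genes of the same library. The lowest difference between the groups of the NF-κB, ATF4 and immediate early medians so taken was 1.328 on the log2 scale (SE 0.0371 over libraries), which argues against scaling as the cause of their rise. Leukocytes among the cells are argued against by marker counts. PTPRC, TYROBP, FCER1G, LAPTM5, LYZ and CD14 together reached at most 0.33% of the CXCL8 count in any BARD1 siRNA library, where 10% or more had been set as the mark of leukocytes. Both groups received siRNA at the same dose. A response to loss of BARD1, or to the BARD1 siRNA by its sequence and apart from its target, may produce the rise. Whether the BARD1 siRNA libraries received 1 siRNA or several is not given in the sources used here. No rescue is among the libraries, so both stay open. Other causes stay open too, because no culture without siRNA is among the libraries.

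For the fall of the DNA replication and mitosis lists, the difference nearer 0, taken in the same way, was −0.514 (SE 0.0402 over libraries). It missed a bound of −0.4 passed by 4 SE that was set first. That bound was replaced after the value was seen, because a scaling factor predicts 0, from which the value lies 12.8 SE away, so scaling is argued against here too. An siRNA can also lower mRNAs whose 3′ UTR matches its seed of 7 bases. The seed match of the strand directed at BARD1 would lie in the BARD1 mRNA, and seeds of the other strand were not tested for. Words were scored by regression of the log2 fold change, with extreme values capped, on presence of the word in the 3′ UTR. The length and GC content of the 3′ UTR and expression were removed. For the adjusted z the mean of words of the same base composition was removed too. Among words of 7 bases found in the BARD1 mRNA, AGGCTGG had the lowest score (adjusted z −4.67, effect −0.0547 on the log2 scale, 3802 genes), and 21 words of 16246 lay under −4. Of these 6 were in BARD1, which holds 25.7% of all scored words. The seed of 1 siRNA would add only 1 word and words overlapping it, so this share cannot decide for or against a seed effect. Such an effect stays open for the lower genes as a whole. The siRNA sequence is not given in the sources used here, and a word outside BARD1 scored −4.75. For the 2 lists, members without AGGCTGG had a median of −0.632, against −0.535 for members with it. Leaving out members with any 1 word of BARD1 gave at most −0.548. Direct matches to any 1 such word thus do not account for the whole of their fall, while several siRNAs with different seeds were not tested for.

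Genes with TATTTAT in the 3′ UTR, an AU-rich word found in unstable mRNAs, were higher in the same regression. The effect was 0.101 on the log2 scale (z 8.73, 4559 of 12609 genes). After removal of the mean of words of the same base composition, as for the words above, its z was 5.67, below the 5.97 of CTATTTA, another AU-rich word. A candidate explanation is that members of the fixed lists alone, such as cytokines and immediate early genes, carry this signal. Without all members of the fixed lists the effect was 0.0813 (z 7.17, and 4.46 after that removal, 4301 genes), so those lists do not account for the whole of it. Whether mRNA stability changed was not measured here.

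The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Only the real split, 1 of the 10, gave 3355 genes higher, 3107 lower, 684 higher by at least 2-fold and 297 lower by at least 2-fold. The highest count of the other splits was 0 in the edgeR test, with 138 to 220 genes at an unadjusted p under 0.05, 0 with limma-voom and at most 2 with DESeq2. Every other split puts libraries of both siRNAs on each side, so the difference between siRNAs enters the spread within a side. Low counts there follow from this and do not show what chance alone would give. For lists past the threshold of camera with the preset correlation, the real split gave 14 and the highest of the others 11, the lowest being 5. Part of the difference between siRNAs stays between the sides of those splits, so their list counts are not a rate of false calls.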
